A study of Mus musculus with 12 samples.

How the data were processed

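Total RNA from limbs of mouse embryos was hybridised to 1-colour Affymetrix oligonucleotide arrays for the mouse genome, on which each transcript is read by a probe set of short probes. The 12 arrays fell into 6 groups of 2, made of 3 stages (11.5, 12.5 and 13.5 days post coitum, dpc) and 2 genotypes, wild type (WT, Lmx1b +/+) and knockout (KO, Lmx1b -/-). Limb buds with the limb girdle were taken at 11.5 and 12.5 dpc, and the distal limb (zeugopod and autopod) at 13.5 dpc. Per the labels, both replicates of a group were pools from different embryos. The series text gives 6 limbs per pool at 11.5 and 13.5 dpc and 3 at 12.5 dpc, whereas the extraction protocol of the labels gives 6 for every sample. The difference could not be settled here. The embryos were labelled C57BL/6. The labels give each stage its own scan series with both genotypes in it, so stage, scan series and, at 13.5 dpc, the dissected part cannot be told apart. Genotypes were compared within a scan series.

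The values used were log2 expression values of 45101 probe sets, deposited by the authors and made with RMA per the submitters' processing notes. Its version is not given in the sources used here. RMA corrects the background, normalizes between arrays and summarises the probes of each probe set. The sorted columns of the deposited table differed by at most 0.242 log2 units at any rank, so the arrays had been brought to nearly 1 distribution before deposit. Scanner files were not used here, so the background correction was not varied. The small number of arrays limits the precision of all values. A dim probe set lies close to background, which compresses its fold changes. The median of all values was 6.28 log2 units.

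The 64 control probe sets were left out. Gene names came from the array platform's annotation table, in which 34945 probe sets named 1 gene, 932 named several and 9160 were without a name in the table used here; the last 2 kinds were kept out of the gene tests. Of the named probe sets, 34741 were matched by gene identifier to a RefSeq gene table of the GRCm38.p6 assembly, which changed 0 symbols. That table served for names and for gene order only, and no coordinates are given because the sources used here name no genome build. Each gene was represented by the probe set with the highest mean over the 12 arrays, which left 18193 genes, 9010 of them with several probe sets.

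Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which left 6 residual and 4.22 prior degrees of freedom. The 9 contrasts were KO minus WT as the mean over the 3 stages and at each stage, the 3 differences of the KO effect between stages, and the 2 changes between consecutive stages in WT. All tests were two-sided, with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05. Standard errors (SE) given with log2 fold changes come from this fit. The replicate numbers were not stated to pair KO and WT pools, and no replicate block was used.

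The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named Lmx1b with each of its probe sets. For the mean comparison it named up to 12 genes in each direction, those with the largest changes past the threshold that had the same sign at all 3 stages and a WT or KO mean over the stages above the median of all values. Had the means of the 6 groups been used there, as the wording of the rule also allows, Gm3515 (-0.88) and Insyn2b (-0.86) would have taken the places of Nrp2 and Cercam. For each stage it named up to 8 in each direction, with both KO arrays above or both below the WT arrays and a group mean above that median, or the 5 smallest p where fewer than 5 genes passed. It named up to 5 genes past the threshold per difference between stages, up to 10 in each direction for each WT change, and up to 4 members of each list, and the smaller changes could be left out of the text. Other genes named below were chosen after their values were seen, and are named because a count was 5 or fewer, because they serve as markers of tissue, sex or stress, or because they lie next to a named gene.

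There were 28 gene lists with 412 entries, of which 387 were measured. They covered patterning and signalling (dorsoventral and BMP, apical ridge and FGF, hedgehog and anteroposterior, WNT and R-spondin, retinoid, distal HOX, proximal limb and girdle, forelimb identity, hindlimb identity), connective tissue (cartilage, bone, joint interzone, tendon and ligament, small leucine-rich proteoglycans, fibrillar and associated collagens), other cells (skeletal muscle, endothelium, erythroid cells, macrophages, surface ectoderm, neurons, Schwann and melanocyte lineage) and axon guidance, Lmx1b targets of kidney and eye, proliferation, hypoxia, early stress response and sex-linked genes. Some genes stand in more than 1 list, such as Kera in the proteoglycan and tendon lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a contrast. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move without setting them against other genes.

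The alternatives were all probe sets, the mean of a gene's probe sets, dim genes left out (12107 genes kept), an intensity trend with a robust prior, renewed quantile normalization, arrays centred on their medians, array quality weights, a threshold of 0.1, a replicate block, only the arrays of a stage, other probe sets of named genes and each array left out in turn. A fit without both KO replicate 2 arrays of 12.5 and 13.5 dpc was added after the data were seen, as was the estimated correlation for the lists in that fit and without KO 12.5 dpc replicate 2. Where a group was left with 1 array, that array was assumed to vary like the other groups. The array quality weights were equal for both arrays of a group, such as 2.07 for KO 11.5 dpc and 0.42 for KO 12.5 dpc. They therefore weighed groups and could not weigh down a single array against its replicate.

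The fit was tested on simulated data with the residual spreads of the 18193 genes and the WT mean of each stage given to both genotypes. In these data 100 genes were changed by 1 and 100 by 2 log2 units in all KO arrays. For KO minus WT, mean over the 3 stages, 99% of the genes changed by 1 and 100% of those changed by 2 were recovered; at 11.5 dpc the shares were 88% and 99%, at 12.5 dpc 93% and 100%, and at 13.5 dpc 91% and 99%. Unchanged genes called were 13 for the mean over the stages, 5 at 11.5 dpc, 13 at 12.5 dpc and 13 at 13.5 dpc. A list of 15 genes shifted by -0.5 log2 units had p = 2.95e-45 by camera on the simulated data and p = 1.72e-05 with an estimated correlation. Of 100 lists without a shift, 4 and 2 had a p under 0.05. The simulated noise was drawn for each gene on its own, with the same spread in all groups, so the genes of a list were uncorrelated. The list values therefore do not tell how either setting of camera behaves on correlated genes. The real replicate pairs varied unequally, from a root mean square difference of 0.140 log2 units across genes for KO 11.5 dpc to 0.356 for KO 12.5 dpc. The shares recovered at each stage therefore do not tell the recovery in the real groups of that stage.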

Results

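The series measured gene expression in limbs of mouse embryos with and without Lmx1b, the LIM homeodomain factor that gives limb mesenchyme its dorsal identity, at 11.5, 12.5 and 13.5 dpc. Each of the 6 groups of stage and genotype held 2 arrays, and each array read RNA pooled from several limbs. The question, from the series title, was which genes differ in expression while the limb acquires its dorsal character. The first 2 stages were sampled as limb buds with the girdle and the last as distal limbs, so values are compared between genotypes within a stage, and between stages only with that limit.

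The targeted gene itself was read by 2 probe sets. On the brighter, 1441729_at, Lmx1b lay at 9.46 ± 0.25 (SD, n = 2, log2) in WT and 5.66 ± 0.08 in KO at 11.5 dpc. It lay at 9.42 ± 0.19 and 6.76 ± 0.37 at 12.5 dpc, and at 10.23 ± 0.05 and 8.18 ± 0.99 at 13.5 dpc. KO minus WT was -3.80 ± 0.35 (SE) at 11.5 dpc (limma adjusted p = 0.00872), -2.66 ± 0.35 at 12.5 dpc (adjusted p = 0.0476) and -2.05 ± 0.35 at 13.5 dpc, where it did not pass (adjusted p = 0.153). Without KO 13.5 dpc replicate 2 it was -2.75 at that stage and passed. The call at 11.5 dpc ended without either KO array or WT replicate 2 of that stage (adjusted p of up to 0.213). The call at 12.5 dpc ended without any 1 array of 11.5 dpc or any 1 WT array (adjusted p of up to 0.156). With an intensity trend and a robust prior, and with a replicate block, both calls ended too (adjusted p from 0.0638 to 0.168). That at 12.5 dpc also ended for the mean of probe sets, after renewed quantile normalization, with array quality weights and from the 4 arrays of the stage alone (adjusted p of up to 0.185), so that 8 of 23 alternatives kept it. The other probe set, 1421769_at, stayed between 5.46 and 5.98 in all 12 arrays, below the median of all values, and passed at no stage. Whether the probes lie inside the deleted part of the gene is not given in the sources used here. In the array labelled KO 13.5 dpc replicate 2 Lmx1b lay at 8.88, between KO replicate 1 at 7.48 and the WT arrays at 10.27 and 10.19 and above each of the other 5 KO arrays.

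Marker genes showed how the pools differed apart from genotype. Pitx1, which specifies the hindlimb, lay between 5.76 and 6.28 in the 8 arrays of 11.5 and 12.5 dpc and between 9.88 and 10.30 in the 4 arrays of 13.5 dpc. Tbx5, the forelimb T-box gene, went from 10.14 to 11.38 in the earlier arrays to 9.47 to 9.93 at 13.5 dpc, although the series text names forelimbs and hindlimbs without separating stages. The array of KO 13.5 dpc replicate 2 held 12.91 log2 units of Hbb-bh1, an embryonic globin, against 10.48 in KO replicate 1 and 9.05 and 8.40 in WT. In the same array the proximal limb gene Meis1 lay at 9.46, against 7.76, 7.12 and 7.01 in the other 3 arrays of that stage. Its correlation across genes was 0.9945 with its replicate, and its mean correlation was 0.9949 with the KO and 0.9948 with the WT arrays of 11.5 dpc. The array of KO 12.5 dpc replicate 2 held the heat shock gene Hspa1a at 9.36, where the other 11 arrays lay between 4.80 and 5.71, and Myh3, an embryonic myosin, at 9.54 against 11.44 in KO replicate 1. The replicate arrays of KO 12.5 dpc differed most of all pairs (root mean square 0.356 log2 units across genes, against 0.140 to 0.267 in the other 5 pairs).

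**Figure D1:**
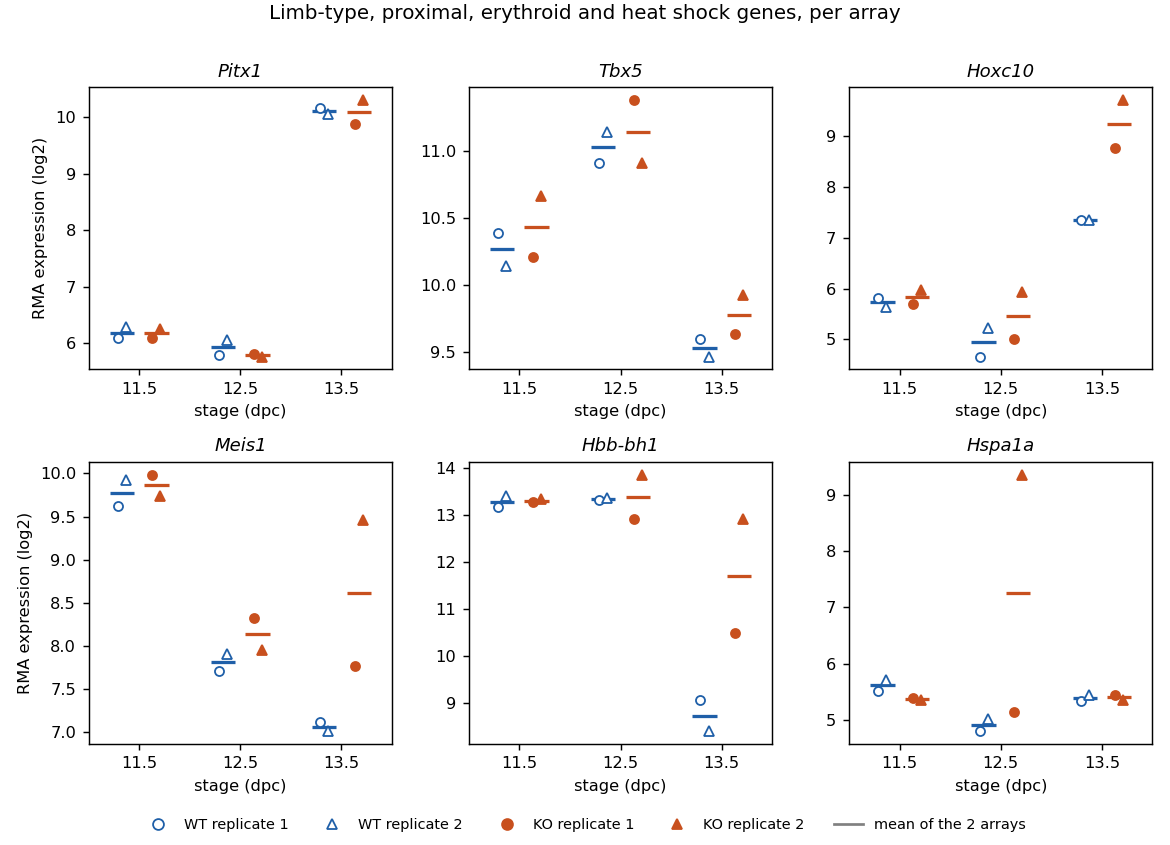
RMA expression (log2, vertical axes) of 6 marker genes against stage (dpc, horizontal axes). Each symbol is 1 array, open for WT and filled for KO, a circle for replicate 1 and a triangle for replicate 2, and each bar is the mean of 2 arrays; Pitx1 was near 6 before 13.5 dpc, Meis1 and Hbb-bh1 were higher in KO 13.5 dpc replicate 2 than in its replicate, and Hspa1a was at 9.36 in KO 12.5 dpc replicate 2 alone.

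Over the 3 stages together, 34 genes were lower in KO limbs and 3 were higher. Kera, which encodes the small leucine-rich proteoglycan keratocan, fell by 2.78 on the log2 scale (SE 0.19, n = 6 arrays per genotype, adjusted p = 3e-04), almost as far as Lmx1b itself (-2.84 ± 0.20). Its neighbour in the genome Lum, encoding lumican, fell by 1.47 (SE 0.22, adjusted p = 0.0306). Emx2, a homeobox gene required for the scapula, fell by 1.61 (SE 0.14, adjusted p = 0.00149), and Apod, encoding the lipocalin apolipoprotein D, fell by 1.25 (SE 0.07, adjusted p = 6.73e-05). Other genes that fell were the transmembrane protein gene Slitrk1 (-1.47 ± 0.21), the cerebellin Cbln2 (-1.18 ± 0.15), the exocytosis regulator Cadps2 (-0.88 ± 0.07), the potassium channel subunit Kcnab1 (-0.83 ± 0.11) and the semaphorin receptor Nrp2 (-0.79 ± 0.11). Cercam (-0.72 ± 0.09) and the uncharacterised transcript E330013P04Rik (-0.97 ± 0.14) fell as well. The 3 higher genes were the paired-box factor Pax9 (0.59 ± 0.09), the lymphatic growth factor Vegfd (0.44 ± 0.06) and the pseudouridine synthase Trub2 (0.32 ± 0.05).

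In all, 37 of 18193 genes passed the threshold in this comparison, 3 higher and 34 lower, and 1249 had an unadjusted p under 0.05. Of the 37, 20 had 39 further probe sets. Of these, 34 had the sign of the called one, among them all 19 that lay above the median of all values. Kera, Emx2 and Cadps2 kept their calls under all 21 alternatives run on each, and Apod and Lmx1b under 21 of 22, all but their dimmer probe sets. The other 10 named genes, Lum and Slitrk1 among them, lost their calls without 7 to 11 of the 12 arrays when each was left out in turn. Both KO arrays and WT replicate 2 of 11.5 dpc were always among these, and all 10 calls also ended with a replicate block. The largest adjusted p over all alternatives ran from 0.135 for Cercam to 0.228 for Lum and 0.915 for Nrp2. Of the higher genes, Pax9 kept its call under 6 of 23 alternatives, Vegfd under 7 of 23 and Trub2 under 4 of 23. The number of called genes was 434 without KO 12.5 dpc replicate 1, 24 without WT 11.5 dpc replicate 1, 15 without KO 13.5 dpc replicate 2, and 14 and 12 without WT 12.5 dpc replicate 1 or 2. It was 11 and 8 without WT 13.5 dpc replicate 1 or 2, 9 without WT 11.5 dpc replicate 2, and 6 and 8 without KO 11.5 dpc replicate 1 or 2. It was 24 when all probe sets were tested and 24 for the mean of each gene's probe sets. Without both KO replicate 2 arrays that stood apart, 38 genes passed, 22 of them among the 37. Cbln2, E330013P04Rik, Cercam, Pax9, Vegfd and Trub2 were not among the 22. On the probe set of each with the smallest change Apod lay at -0.24, Nrp2 at -0.12, Pax9 at 0.28 and Trub2 at 0.19, and none of these passed.

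**Figure D2:**
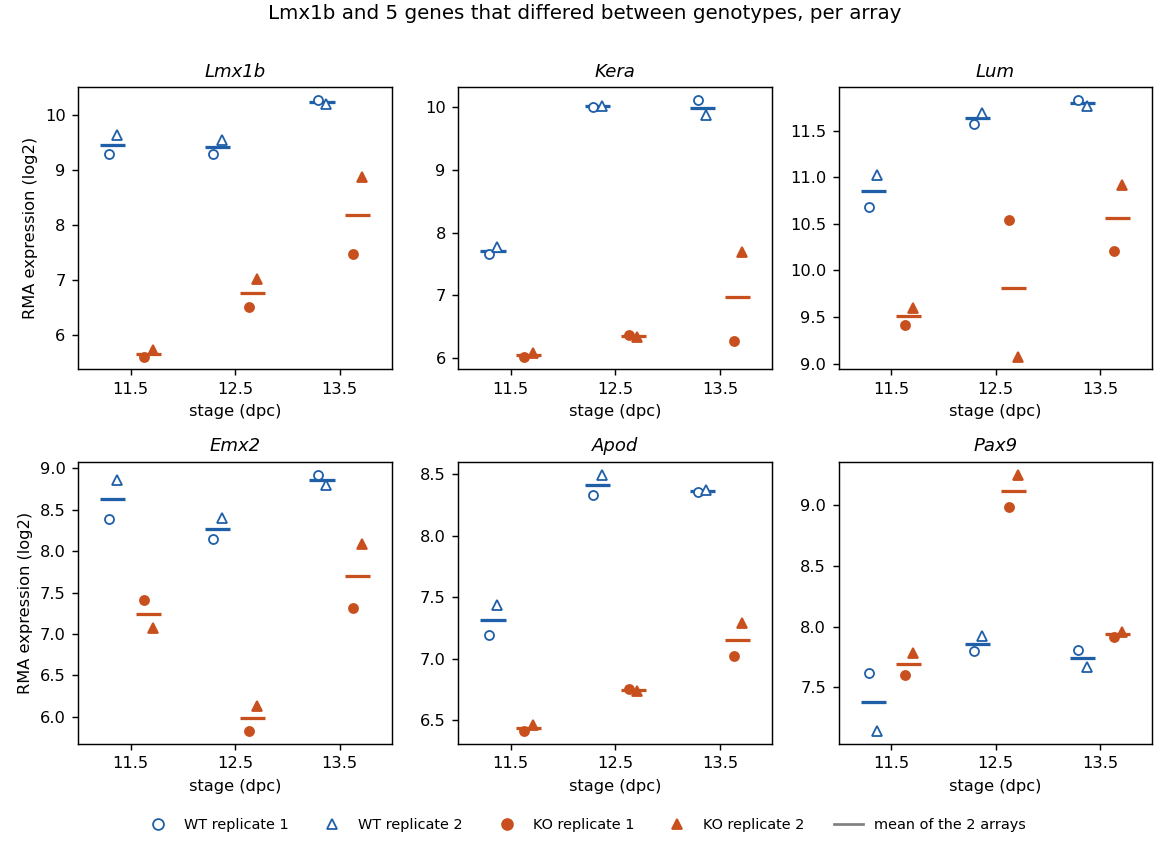
RMA expression (log2, vertical axes) of Lmx1b and 5 genes called in KO minus WT over the 3 stages, against stage (dpc, horizontal axes). Each symbol is 1 array, open for WT and filled for KO, a circle for replicate 1 and a triangle for replicate 2, and each bar is the mean of 2 arrays; Kera, Lum, Emx2 and Apod lay lower in both KO arrays than in both WT arrays at every stage, and Pax9 differed most at 12.5 dpc (1.26 ± 0.15).

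Among the gene lists, cartilage had the smallest camera p in the comparison over the 3 stages, though not the largest median or mean difference. All 22 measured members had a negative difference, with a median of -0.41 (camera adjusted p = 1.88e-16; adjusted p = 0.319 with an estimated correlation). None of them passed over all genes, and 17 were lower when adjusted over the list alone. Examples are the link protein gene Hapln1 (-0.80 ± 0.16), the matrilin Matn1 (-1.31 ± 0.30), chondromodulin, encoded by Cnmd (-1.21 ± 0.28), and aggrecan, encoded by Acan (-0.90 ± 0.22). Without both KO replicate 2 arrays that stood apart, the cartilage median was -0.19, with 22 members still negative (adjusted p = 4.16e-09; adjusted p = 0.784 with an estimated correlation). Of the 14 small leucine-rich proteoglycan genes, 12 had a negative difference and the median was -0.29 (adjusted p = 2.36e-07; adjusted p = 0.319 with an estimated correlation). Kera and Lum passed over all genes and 5 members were lower when adjusted over the list alone. Decorin, encoded by Dcn, lay at -1.03 ± 0.22 and Epyc at -0.82 ± 0.18 without passing. Without both KO arrays the median of this list was -0.04 (adjusted p = 0.0216; adjusted p = 0.784 with an estimated correlation).

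Other connective tissue, cell type and signalling lists were called over the 3 stages too, and each of the 14 calls was lost with an estimated correlation. Tendon and ligament genes had a median of -0.26 (adjusted p = 0.0145; adjusted p = 0.586 with an estimated correlation), with Kera passing over all genes and 4 lower and 1 higher when adjusted over the list alone. The tendon factor Mkx lay at -0.78 ± 0.17 and tenomodulin, encoded by Tnmd, at -0.64 ± 0.17. Without both KO arrays their median was -0.02 (adjusted p = 0.971). Joint interzone genes had a median of -0.22 (adjusted p = 0.0158; adjusted p = 0.586 with an estimated correlation), with 0 passing over all genes and 4 lower when adjusted over the list alone. Among them was the joint growth factor Gdf5 (-0.92 ± 0.20). Fibrillar and associated collagens (median -0.13), endothelium (-0.10), dorsoventral and BMP patterning (-0.10), neurons (-0.14) and the retinoid pathway (-0.07) were also called lower, with adjusted p from 0.00489 to 0.0395 (adjusted p from 0.319 to 0.586 with an estimated correlation). No member of these 5 passed over all genes. Adjusted over the list alone, 2 dorsoventral and BMP genes and 1 neuronal gene were lower. Erythroid cells (median 0.30), forelimb identity (0.27), hindlimb identity (0.11), apical ridge and FGF signalling (0.05) and proliferation (0.03) were called higher, with adjusted p from 1.5e-05 to 0.0324 (adjusted p from 0.319 to 0.586 with an estimated correlation). None of their members passed over all genes. Adjusted over the list alone, 2 hindlimb genes were higher, and 3 apical ridge and FGF genes were higher and 1 lower.

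The list calls were repeated without the arrays that stood apart. Without both KO replicate 2 arrays, 4 of the 14 calls remained, those of cartilage, small leucine-rich proteoglycans, hindlimb identity (adjusted p = 0.0472) and forelimb identity (adjusted p = 0.024). The erythroid median was then 0.015 (adjusted p = 0.231), the collagen median was 0.02 (adjusted p = 0.0874), and skeletal muscle was called higher (median 0.10, adjusted p = 4.74e-06). None of these 5 calls held with an estimated correlation (adjusted p = 0.784 for each). Leaving out KO 12.5 dpc replicate 2 alone ended the calls of tendon and ligament, joint interzone, fibrillar and associated collagens, endothelium, neurons, retinoid pathway, apical ridge and FGF signalling and proliferation. Leaving out KO 13.5 dpc replicate 2 alone ended those of tendon and ligament, joint interzone, fibrillar and associated collagens, neurons, retinoid pathway, proliferation and forelimb identity. The largest adjusted p over the alternatives was 0.971 for tendon and ligament, 0.815 for collagens, 0.758 for proliferation, 0.757 for the retinoid pathway, 0.533 for forelimb identity, 0.367 for joint interzone and for apical ridge and FGF signalling, 0.238 for endothelium and 0.223 for neurons. On ranks, 6 of the 14 calls ended, those of tendon and ligament, hindlimb identity, joint interzone, the retinoid pathway, neurons and apical ridge and FGF signalling (adjusted p from 0.0553 to 0.172, and 0.165 for hindlimb identity). Hindlimb identity also lost its call without WT 12.5 dpc replicate 1 (adjusted p = 0.0522), as did forelimb identity without replicate 1 of either genotype at 12.5 dpc. Endothelium lost it without WT 11.5 dpc replicate 2 or WT 12.5 dpc replicate 1, neurons without 5 and the retinoid pathway without 7 of the 12 arrays. By fry, which does not set a list against other genes, 0 lists moved in 1 direction at any stage or over the 3 stages. Counting change in either direction, fry called 4 lists over the 3 stages and 0, 3 and 3 at 11.5, 12.5 and 13.5 dpc. In the WT changes it called 6 lists in 1 direction from 11.5 to 12.5 dpc and 5 from 12.5 to 13.5 dpc. Counting either direction, the WT numbers were 21 and 25.

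The 14 lists not called over the 3 stages had adjusted p from 0.112 to 0.914. Their medians were 0.15 for proximal limb and girdle genes, 0.05 for distal HOX genes, -0.06 for WNT and R-spondin signalling, -0.09 for axon guidance, -0.07 for the Schwann and melanocyte lineage, 0.01 for surface ectoderm, -0.57 for sex-linked genes, -0.04 for Lmx1b targets of kidney and eye, 0.03 for early stress response, 0.02 for hypoxia, -0.06 for skeletal muscle, -0.0056 for macrophages, -0.08 for hedgehog and anteroposterior patterning and -0.02 for bone. In the proximal list Emx2 fell and Pax9 rose over all genes, and 3 members were higher and 3 lower when adjusted over the list alone. No member of the other 13 passed over all genes. Adjusted over the list alone, 1 distal HOX gene was higher, 1 axon guidance gene was higher and 4 lower, 1 hedgehog and anteroposterior gene was higher and 2 lower, and 1 gene each was lower among skeletal muscle genes and Lmx1b targets. The proximal mean was -0.06 while the median and test pointed up. For skeletal muscle and macrophages the test pointed up against a negative median and mean. For bone the mean was 0.02 with the median and test pointing down.

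**Figure D3:**
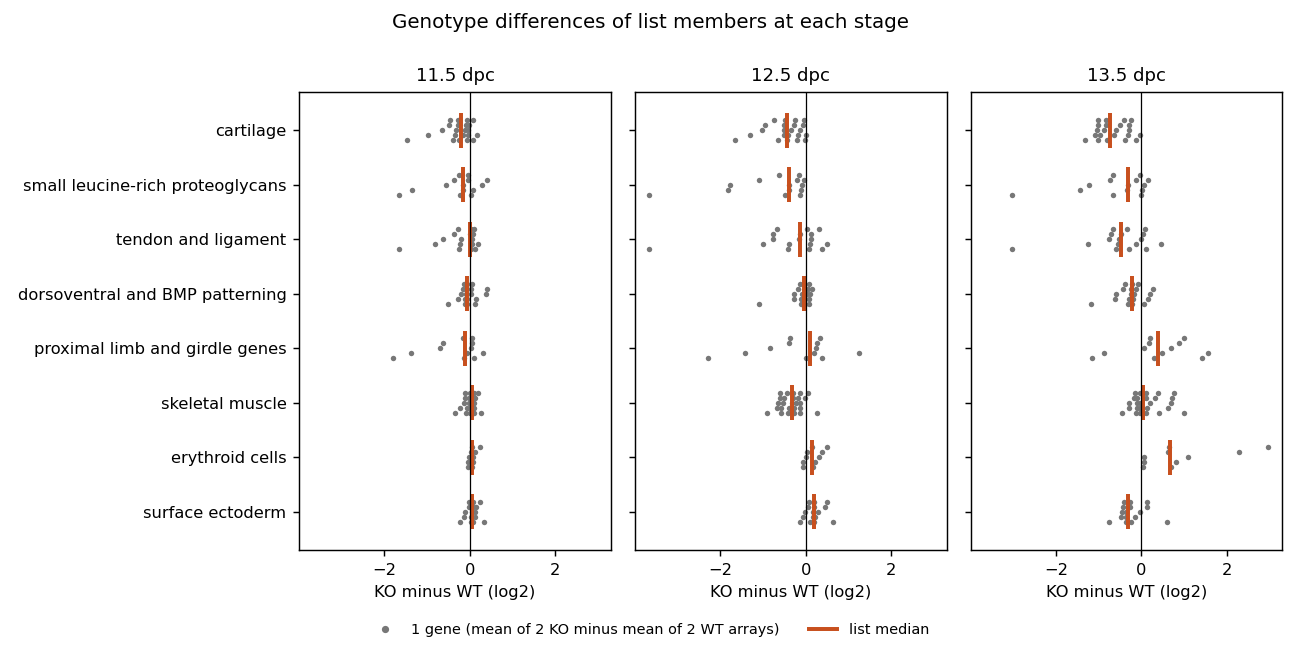
KO minus WT differences (log2, horizontal axes) of the measured members of 8 gene lists (vertical axis) at 11.5, 12.5 and 13.5 dpc. Each point is 1 gene, as the mean of 2 KO arrays minus the mean of 2 WT arrays, and each bar is the list median; the cartilage median was -0.22, -0.43 and -0.73 at the 3 stages, and the skeletal muscle median was -0.31 at 12.5 dpc only.

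At 11.5 dpc, the earliest stage, 3 genes passed and all were lower in KO. Besides Lmx1b these were Cadps2 (-1.30 ± 0.13, adjusted p = 0.00872) and Pdzrn4, a gene of a PDZ and RING finger protein (-1.36 ± 0.16, adjusted p = 0.0346), whose highest group mean, 5.19 in WT, was below the median of all values. Apod (-0.88 ± 0.12, adjusted p = 0.0897) and the calcium binding protein gene Calb2, encoding calretinin (-1.19 ± 0.20, adjusted p = 0.535), had the next smallest p and did not pass. Genes expressed in the proximal limb and girdle had a median of -0.11 (adjusted p = 0.0284; adjusted p = 0.848 with an estimated correlation). Of these, 0 passed over all genes and 2 were lower when adjusted over the list alone. Pax1, a girdle factor, lay at -1.81 ± 0.38 (adjusted p = 1). Cartilage (median -0.22, adjusted p = 0.0116), endothelium (-0.14, adjusted p = 0.0187) and neurons (-0.29, adjusted p = 0.0187) were also called lower, with 0 members passing over all genes or adjusted over the list alone (adjusted p from 0.608 to 0.848 with an estimated correlation). Without KO 11.5 dpc replicate 1 or WT 11.5 dpc replicate 2 the calls of cartilage and endothelium ended, with adjusted p of up to 0.306 and 0.734. Those of neurons (up to 0.414) and proximal genes (up to 0.0616) ended without 4 of the 12 arrays each, KO 11.5 dpc replicate 2 among them for both. On ranks the calls of endothelium, neurons (adjusted p = 0.0595 for both) and proximal genes (adjusted p = 0.403) ended, and with dim genes left out that of proximal genes (adjusted p = 0.26). Macrophage genes (median 0.14, adjusted p = 3e-05) and apical ridge and FGF genes (0.12, adjusted p = 0.000754) were called higher, likewise with 0 members passing either way (adjusted p = 0.249 with an estimated correlation for both). Fgf18 lay at 0.62 ± 0.20 and the macrophage receptor gene Adgre1 at 0.31 ± 0.13. The test over genes used limma, with 298 genes at an unadjusted p under 0.05. The count was 0 without KO 11.5 dpc replicate 1, KO 11.5 dpc replicate 2 or WT 11.5 dpc replicate 2, 5 without either KO 13.5 dpc array, 14 with array quality weights, and 7 without both KO replicate 2 arrays that stood apart. With a replicate block the count was 0, and from the 4 arrays of the stage alone Cadps2 and Pdzrn4 lost their calls (adjusted p of up to 0.252). Pdzrn4 also lost its call without any 1 array of 12.5 dpc or either WT 13.5 dpc array (largest adjusted p over all alternatives 0.501).

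At 12.5 dpc, 7 genes passed, 2 higher and 5 lower in KO. Kera lay at 10.02 in WT and 6.35 in KO, a difference of -3.67 ± 0.33 (adjusted p = 0.00423). Emx2 (-2.29 ± 0.25, adjusted p = 0.016), Apod (-1.67 ± 0.12, adjusted p = 0.000904), Cadps2 (-0.99 ± 0.13, adjusted p = 0.0364) and Lmx1b were the other lower genes. Pax9 (1.26 ± 0.15, adjusted p = 0.0364) and Nfkbiz, encoding an inhibitor of NF-kappaB (0.77 ± 0.10, adjusted p = 0.0364), were higher. All 14 small leucine-rich proteoglycan genes had a negative difference (median -0.39, adjusted p = 2.4e-05; adjusted p = 0.949 with an estimated correlation), with Kera passing over all genes and 6 lower when adjusted over the list alone. Epyc lay at -1.77 ± 0.31 and Lum at -1.83 ± 0.38. The 2 KO arrays differed widely for Lum, at 9.81 ± 1.04 (SD) in KO and 11.64 ± 0.09 in WT. Cartilage genes had a median of -0.43 (adjusted p = 3.23e-05; adjusted p = 0.962 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Skeletal muscle genes had a median of -0.31 (adjusted p = 0.0494; adjusted p = 0.962 with an estimated correlation), with 0 passing over all genes and 1, the muscle factor Myf6 (-0.60 ± 0.11), lower when adjusted over the list alone. Surface ectoderm had a median of 0.18 (adjusted p = 0.00987; adjusted p = 0.962 with an estimated correlation), with 0 passing over all genes and 1, the desmosome gene Dsp (0.63 ± 0.15), higher when adjusted over the list alone.

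The list values at 12.5 dpc moved with KO replicate 2, the array with high Hspa1a. Without both KO replicate 2 arrays the skeletal muscle median turned to 0.30 (adjusted p = 4.37e-05, called higher), the cartilage median was -0.08 (adjusted p = 0.5) and that of small leucine-rich proteoglycans -0.16 (adjusted p = 0.102). Surface ectoderm was no longer called (adjusted p = 0.093), while tendon and ligament (median 0.28, adjusted p = 0.0214) and fibrillar and associated collagens (median 0.41, adjusted p = 8.2e-08) were called higher. None of these 3 higher calls held with an estimated correlation (adjusted p = 0.789 for skeletal muscle and for tendon and ligament, adjusted p = 0.573 for collagens). Without KO 12.5 dpc replicate 2 alone, cartilage and small leucine-rich proteoglycans also lost their calls, and skeletal muscle was called higher (adjusted p = 7.44e-05; adjusted p = 0.942 with an estimated correlation). The skeletal muscle call further ended without any 1 of 8 other arrays (adjusted p of up to 0.402, without WT 12.5 dpc replicate 2). Surface ectoderm lost its call without replicate 1 of either genotype at 12.5 dpc (adjusted p of up to 0.935). Without both KO replicate 2 arrays the number of called genes was 94, with 55 higher and 39 lower and 6 of the 7 among them. It was 515 without KO 12.5 dpc replicate 1, 37 without KO 12.5 dpc replicate 2, 4 and 1 without WT 12.5 dpc replicate 1 or 2, 3 without either KO 11.5 dpc array, 4 without either KO 13.5 dpc array and 2 without either WT 13.5 dpc array. Apod kept its call whichever array was left out, Kera lost it without WT 12.5 dpc replicate 2 (adjusted p = 0.0628), and Emx2 without any 1 WT array of 12.5 or 13.5 dpc (adjusted p of up to 0.101). Cadps2, Pax9 and Nfkbiz lost theirs without 8 to 10 of the 12 arrays, the WT arrays of 12.5 and 13.5 dpc always among them. With a replicate block all of the 7 but Apod lost their calls (adjusted p of 0.0844 for Kera and up to 0.245 for Nfkbiz), and from the 4 arrays of the stage alone all but Kera (adjusted p of 0.156 for Apod and Emx2 and up to 0.957). On other probe sets, none of which passed, Apod lay at -0.64, Pax9 as low as 0.23 and Nfkbiz at 0.20 and 0.29. The count was 63 over all probe sets, 4 for the mean of probe sets, 4 after renewed quantile normalization, 2 with array quality weights and 1 from the 4 arrays of the stage alone, against 1981 genes at an unadjusted p under 0.05.

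At 13.5 dpc, 5 genes passed and all were lower in KO. Kera (-3.02 ± 0.33, adjusted p = 0.0104), Insyn2b, a gene of an inhibitory synapse factor (-1.53 ± 0.14, adjusted p = 0.00642), and Apod (-1.21 ± 0.12, adjusted p = 0.00642) met the naming rule. The other 2 were the forkhead factor Foxf2 (-1.51 ± 0.12, adjusted p = 0.00409) and Nwd2 (-1.01 ± 0.10), whose group means did not exceed the median of all values. All 22 cartilage genes had a negative difference (median -0.73, adjusted p = 1.58e-15; adjusted p = 0.262 with an estimated correlation). Of these, 0 passed over all genes and 13 were lower when adjusted over the list alone, among them Sox6 (-0.83 ± 0.21) and Hapln1 (-1.08 ± 0.29). Dorsoventral and BMP genes had a median of -0.23 (adjusted p = 1.43e-05; adjusted p = 0.171 with an estimated correlation), with 0 passing over all genes and 4 lower when adjusted over the list alone, such as the BMP receptor gene Bmpr1b (-0.60 ± 0.10) and the homeobox gene Msx1 (-0.62 ± 0.16). Fibrillar collagens (median -0.34), small leucine-rich proteoglycans (-0.32) and tendon and ligament genes (-0.49) were called lower as well, with adjusted p from 1.43e-05 to 0.000243 (adjusted p from 0.361 to 0.46 with an estimated correlation). Kera was their member that passed over all genes. Adjusted over the list alone, 0 collagens, 3 proteoglycan genes and 2 tendon genes were lower.

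Lists of blood, proximal limb and limb type markers were also called at this stage, and none of these calls held with an estimated correlation. Erythroid genes had a median of 0.67 (adjusted p = 7.78e-07; adjusted p = 0.262 with an estimated correlation), with Hbb-bh1 at 2.97 ± 0.60, 0 genes passing over all genes and 1 higher when adjusted over the list alone. Proximal limb and girdle genes had a median of 0.38 (adjusted p = 8.3e-05; adjusted p = 0.262 with an estimated correlation), with 0 passing over all genes and 5 higher and 1 lower when adjusted over the list alone. Shox2 lay at 1.43 ± 0.35 and Hoxd9 at 0.87 ± 0.17, while Emx2 lay at -1.16 ± 0.25. The level of Shox2 was 11.66 in KO replicate 2, which stood apart, and 10.16 in KO replicate 1, against 9.61 and 9.35 in WT. Hindlimb identity had a median of 0.34 (adjusted p = 8.3e-05; adjusted p = 0.171 with an estimated correlation), with 0 passing over all genes and 3 higher when adjusted over the list alone. Hoxc10 lay at 1.89 ± 0.33 and Isl1 at 1.48 ± 0.31, but Pitx1 at -0.03 ± 0.15. Against the WT mean, KO replicate 1 had Hoxc10 at 1.43, Isl1 at 0.86 and Pitx1 at -0.24. In KO replicate 2 these genes were at 2.36, 2.10 and 0.19. Forelimb identity (median 0.93), proliferation (0.11) and skeletal muscle (0.03) were called higher, and macrophages (-0.20), surface ectoderm (-0.31), WNT and R-spondin signalling (-0.22) and the retinoid pathway (-0.17) lower, with adjusted p from 0.00135 to 0.0257 (adjusted p from 0.171 to 0.569 with an estimated correlation). None of their members passed over all genes. Adjusted over the list alone, 3 muscle genes were higher, among them Lbx1 (0.72 ± 0.14), and 1 gene each was lower among macrophage, ectoderm and WNT genes.

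The 13.5 dpc values also moved with the array of KO 13.5 dpc replicate 2. Without both KO replicate 2 arrays, forelimb identity, proliferation, skeletal muscle and the retinoid pathway were no longer called (adjusted p from 0.268 to 0.578). The erythroid median was 0.24 (adjusted p = 0.000272), the proximal median 0.13 (adjusted p = 0.0428) and the cartilage median -0.38 (adjusted p = 9.21e-09). With an estimated correlation none of these 3 was called (adjusted p from 0.393 to 0.48). Without KO 13.5 dpc replicate 2 alone, these 4 lists (adjusted p from 0.214 to 0.688), fibrillar and associated collagens (adjusted p = 0.147), small leucine-rich proteoglycans and tendon and ligament (adjusted p = 0.111 for both) lost their calls. Without KO 13.5 dpc replicate 1, macrophages, surface ectoderm and WNT and R-spondin signalling lost theirs (adjusted p from 0.0847 to 0.0989), and the retinoid pathway did without WT 13.5 dpc replicate 2 (adjusted p = 0.181). The retinoid call also ended with dim genes left out (adjusted p = 0.0609), and that of skeletal muscle on ranks (adjusted p = 0.084). Kera and Apod lost their calls without either WT 13.5 dpc array (adjusted p of up to 0.223 and 0.155), and Insyn2b without either of these or KO 13.5 dpc replicate 2 (adjusted p of up to 0.134). All 3 also lost their calls with a replicate block (adjusted p from 0.105 to 0.122), Kera from the 4 arrays of the stage alone (adjusted p = 0.0718) and Apod for the mean of its probe sets (adjusted p = 0.152). On another probe set Apod lay at -0.16 and did not pass. The number of called genes was 11 in that fit, 56 without KO 13.5 dpc replicate 1, 43 without either KO 12.5 dpc array, 8 without either WT 12.5 dpc array, and 0 and 1 without WT 13.5 dpc replicate 1 or 2. It was 14 with an intensity trend and 11 from the 4 arrays of the stage alone, with 1073 genes at an unadjusted p under 0.05.

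The difference between genotypes was also compared between stages. Kera, Emx2, Apod and Cadps2 lay lower in KO at all 3 stages. Kera went from -1.66 at 11.5 dpc to -3.67 and -3.02 at the later stages, and Cadps2 from -1.30 to -0.99 and -0.36. No gene passed the limma test of a difference of the KO effect between 12.5 and 11.5 dpc (smallest adjusted p = 0.254; 1132 genes at an unadjusted p under 0.05), between 13.5 and 12.5 dpc (0.339; 1546 genes) or between 13.5 and 11.5 dpc (0.07; 377 genes). The gene with the smallest p in the last of these was Calb2, at -1.19 at 11.5 dpc and 1.38 at 13.5 dpc. The 3 counts were 38, 46 and 0 without KO 12.5 dpc replicate 1, 0, 15 and 0 without KO 12.5 dpc replicate 2, 1, 1 and 12 without KO 13.5 dpc replicate 1, and at most 1 without any other array. Genes called at 1 stage had the same sign at the others in all cases but Nfkbiz, which was higher in KO at 12.5 dpc and lay at -0.30 ± 0.10 at 11.5 dpc. Across all genes, which are not independent replicates, Spearman's correlation of the differences was -0.03 between 11.5 and 12.5 dpc, 0.20 between 11.5 and 13.5 dpc and -0.0079 between 12.5 and 13.5 dpc. Pearson's correlation was 0.13, 0.25 and 0.13, so the sign of 2 of the 3 pairs differed between the measures. Spearman's was 0.05, 0.23 and 0.04 when dim genes were left out, which turned the same 2 from negative to positive. Of the 100 genes with the smallest p at 1 stage, 56 to 78 had the same sign at another. The stages share no array, and with 6 arrangements of the arrays of a stage no p under 0.05 could be had.

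The WT limbs were also compared between stages, which differ in scan series too. From 11.5 to 12.5 dpc, 1213 genes rose and 2390 fell. Among the named rises were the fast myosin light chain gene Mylpf (2.00 ± 0.43), Myh3 (2.01 ± 0.44) and Matn1 (1.88 ± 0.53), and Kera itself rose by 2.30 ± 0.33. Among the named falls were the patterning genes Pax1 (-2.67 ± 0.38), Irx3 (-2.55 ± 0.35), Hoxb5 (-2.57 ± 0.40) and Fgf8, the ridge growth factor (-2.13 ± 0.45). The lists of cartilage (median 0.61), small leucine-rich proteoglycans (0.76), skeletal muscle (0.83), tendon and ligament (0.45) and fibrillar collagens (0.31) were called higher and surface ectoderm (-0.76) lower, with adjusted p from 7.23e-07 to 0.0441 (adjusted p from 0.874 to 0.951 with an estimated correlation). Of their members, 10 cartilage, 5 proteoglycan, 11 muscle, 3 tendon and 0 collagen genes rose and 11 ectoderm genes fell over all genes, as did 2 muscle genes and 1 tendon gene. Adjusted over the list alone, 13 cartilage, 9 proteoglycan, 17 muscle, 5 tendon and 0 collagen genes rose, and 12 ectoderm, 2 muscle, 1 cartilage and 1 tendon genes fell. The tendon and ligament call ended without WT 12.5 dpc replicate 2, and that of fibrillar and associated collagens without WT 11.5 dpc replicate 1 or either WT 12.5 dpc array (adjusted p of up to 0.0665 and 0.142). On other probe sets Ttn (2.5 ± 0.42), Meis1 (-1.96 ± 0.40) and Igdcc3 (-2.27 ± 0.35) had the opposite sign, at -0.022, 0.28 and 0.22, and Pax1 lay at -0.13 without passing (adjusted p = 0.626). The total of 3603 genes became 1401 and 814 without WT 11.5 dpc replicate 1 or 2, 2031 and 2211 without WT 12.5 dpc replicate 1 or 2, and 5950 without both KO replicate 2 arrays.

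From 12.5 to 13.5 dpc, when the dissected part changed too, 2635 genes rose and 1963 fell in WT. Pitx1 rose by 4.18 ± 0.15 (adjusted p = 7.94e-07), Hoxc10 by 2.41 ± 0.33, Tnmd by 2.67 ± 0.30 and the keratin gene Krt1 by 2.18 ± 0.24. Hbb-bh1 (-4.62 ± 0.60), the proximal gene Shox2 (-2.19 ± 0.35) and the muscle gene Tnnt2 (-2.21 ± 0.41) fell. Surface ectoderm (median 1.24), fibrillar collagens (0.53), hindlimb identity (2.09), WNT and R-spondin signalling (0.36), cartilage (0.40), joint interzone (0.50) and macrophages (0.25) were called higher, and skeletal muscle (-1.36), erythroid cells (-1.25), proliferation (-0.18) and forelimb identity (-1.39) lower, with adjusted p from 7.78e-08 to 0.0441 (adjusted p from 0.429 to 0.691 with an estimated correlation). Over all genes 13 ectoderm, 7 collagen, 3 hindlimb, 11 WNT, 7 cartilage, 2 joint and 3 macrophage genes rose. Of the lower lists, 16 muscle, 6 erythroid, 2 proliferation and 3 forelimb genes fell, while 1 muscle gene rose and 1 WNT gene fell. The numbers adjusted over the list alone were 14, 8, 3, 11, 7, 4 and 3 higher and 19, 6, 1 and 3 lower. The calls of cartilage, joint interzone and macrophages ended without WT 12.5 dpc replicate 2 (adjusted p = 0.0527 for the first 2 and 0.241 for macrophages) and with dim genes left out (adjusted p of 0.0709, 0.092 and 0.0588). That of joint interzone also ended without WT 12.5 dpc replicate 1 (adjusted p = 0.0995) or WT 13.5 dpc replicate 2 (adjusted p = 0.0594), and that of macrophages without the latter, with a replicate block and on ranks (adjusted p from 0.0511 to 0.0593). Ttn (-2.33 ± 0.42) lay at 0.15 on another probe set, Tnnt2 at -0.20 without passing (adjusted p = 0.344), and Pitx1 at 2.76, which passed. The makeup of the pools by limb type is not given by stage. With Pitx1 near 6 in all 8 earlier arrays, limb type and stage cannot be told apart for Pitx1, Hoxc10 and the hindlimb and forelimb lists. The total of 4598 genes became 2741 without WT 12.5 dpc replicate 1, 2087 and 1663 without WT 13.5 dpc replicate 1 or 2, and 6940 without both KO replicate 2 arrays.

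Genes next to Lmx1b were compared with all others, since a targeted allele can carry flanking DNA. Of 127 tested genes within 150 annotated genes on either side, 1 was called over the 3 stages, Cercam, against 34 of 18017 elsewhere (odds ratio 4.2, 95% interval 0.10 to 25.4, Fisher's exact test, two-sided p = 0.218). Within 300 genes there were 2 of 242, Cercam and Trub2 (exact p = 0.0791), and within 50 genes 0 of 47 (exact p = 1). Both genes differed by about as much at each stage, Cercam by -0.59, -0.74 and -0.83 and Trub2 by 0.32, 0.30 and 0.34.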

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

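The tests of 11.5 dpc RNA in the pool and in replicate 2, of slower development, of Pitx1 with Tbx4 and of proximal tissue in the KO pools were chosen after the result was seen, and that of proximal tissue in the single pool when a related value, the 95% below, was known. Calb2, which encodes calretinin, lay lower in both KO arrays than in both WT arrays at 11.5 and 12.5 dpc and higher at 13.5 dpc. The difference of its KO effect was 2.57 ± 0.29 between 13.5 and 11.5 dpc (limma adjusted p = 0.07) and 1.82 ± 0.29 between 13.5 and 12.5 dpc (adjusted p = 0.339). Nfkbiz was higher in both KO arrays at 12.5 and 13.5 dpc and lower at 11.5 dpc, with a difference of 1.07 ± 0.14 between 12.5 and 11.5 dpc (adjusted p = 0.254) and 0.39 ± 0.14 between 13.5 and 11.5 dpc (adjusted p = 1). None of the 4 passed the test of the difference. With 2 arrays against 2, chance gives opposite separation in 5.56% of comparisons of genes not chosen for their values. Most of the 19 genes screened had been chosen for the same sign at all 3 stages, so the 4 cannot be set against a number expected by chance.

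Among the 10092 probe sets without a single gene name, 8 passed in KO minus WT over the 3 stages when all probe sets were tested, 4 higher and 4 lower. The lowest were 1435146_s_at (-0.98 ± 0.09, adjusted p = 0.00319) and 1435145_at (-0.64 ± 0.08), and the highest were 1453540_at (0.81 ± 0.11) and 1443201_at (0.53 ± 0.08). Of the 8, only 1443201_at had a mean level (6.37) above the median of all values. The lowest 2 were dim, with mean levels of 3.81 and 3.53, and 1453540_at had 5.27.

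The array of KO 13.5 dpc replicate 2 stood apart from its group, with Lmx1b at 8.88 and a profile close to 11.5 dpc of both genotypes. More proximal tissue in this pool was tested on 100 genes. They were the highest in 11.5 dpc WT relative to 12.5 dpc, dissected in the same way, and to the other 13.5 dpc levels. Of the 100, 73% lay above all those levels by over 1 residual SD, past the bound set to count against it. But the 100 include proximal genes such as Meis1. It lay at 9.77 in 11.5 dpc WT, 9.46 in this array and at most 8.14 in the levels compared. More proximal tissue would raise such genes too, so the share cannot decide. The ridge gene Fgf8, also among the 100, lay at 7.43 in this array against at most 6.05 in the levels compared. Slower development is argued against, on 5 genes alone. Of these 5, lower in KO over 11.5 and 12.5 dpc, 4 (80%) lay above every other KO level by over 1 residual SD. A candidate explanation is RNA of 11.5 dpc WT limbs in the pool. The median share over the 100 genes most typical of that group was 55.1% (95% bootstrap interval 49.3 to 57.7). The interval comes from resampling these genes, picked for their excess in 11.5 dpc WT and read from 1 array. It does not measure the error of a tissue share. The median share would put Lmx1b at 8.88, where it was measured, against 6.75 for that share of KO 11.5 dpc RNA. Lmx1b is 1 gene, and others did not follow such a mixture. Hoxc10 was at 9.71 in this array, above replicate 1 (8.78) and 11.5 dpc WT (5.82 and 5.65). Isl1 was at 7.43, above replicate 1 (6.19) and 11.5 dpc WT (6.58 and 6.74). Kera, at 7.69, had the level of 11.5 dpc WT (7.65 and 7.77), with replicate 1 at 6.27. The Y-linked gene Uty was at 4.79 in this array and in replicate 1, against 7.02 and 7.22 in 11.5 dpc WT. Kdm5d was at 4.80, with replicate 1 at 2.88 and 11.5 dpc WT at 7.85 and 7.81. Eif2s3y was at 4.65, with replicate 1 at 2.89 and 11.5 dpc WT at 5.88 and 6.64. Y-linked levels also depend on the sexes of the pooled embryos, so they bear only on the extracts measured here. The share itself was measured with the 11.5 dpc WT extracts of these arrays. RNA of the very 11.5 dpc extracts measured here is argued against, since Pitx1 and Tbx4, low in those, lay 0.18 above replicate 1 on average (SE 0.16), where that share needs -0.93. In a first version these genes were a condition of the share test too, which then left 11.5 dpc RNA undecided. The condition was removed after the result was seen. RNA of 13.5 dpc WT limbs was tried on 3 genes and then on 100. As the only source it was set aside, because 95% of those 100 lay above both replicate 1 and 13.5 dpc WT. These 100 had been chosen as higher in 11.5 dpc WT than in both, so a part of 13.5 dpc WT RNA stays open. Lmx1b alone would need a share of 28.5% of it.

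The hindlimb list was called higher in KO at 13.5 dpc (adjusted p = 8.3e-05; adjusted p = 0.171 with an estimated correlation), with 0 members passing over all genes and Pitx1 at -0.03. A larger share of hindlimb tissue in the KO pools would raise Pitx1 and Tbx4 too, and neither was higher in both KO arrays. Against the WT mean Pitx1 lay at -0.24 in replicate 1 and 0.19 in replicate 2, and Tbx4 at 0.05 and -0.01. The other list members, Hoxc9 (0.35 and 0.33), Hoxc10 and Isl1, were higher in both. Such a share is argued against only weakly by the forelimb gene Tbx5, which lay at 0.25 ± 0.19 rather than lower. Tbx5 was at 9.93 in KO replicate 2 and 9.63 in replicate 1, against 9.60 and 9.47 in WT. RNA of 11.5 dpc limbs, with Tbx5 from 10.14 to 10.66, would raise it in replicate 2, which leaves replicate 1 alone to judge by. RNA of 11.5 dpc WT limbs in replicate 2 stays open for a part of the difference at most. In replicate 1 the median over the 5 measured hindlimb genes was 0.35 above WT. Of the 4 genes higher in replicate 2, 3 were higher in replicate 1 too. Hoxc10 lay at 5.82 and 5.65 in 11.5 dpc WT, below replicate 1 (8.78), yet replicate 2 had 9.71. Isl1 was at 7.43 in replicate 2, above both replicate 1 (6.19) and 11.5 dpc WT (6.58 and 6.74). On these single values, RNA with the 11.5 dpc WT levels measured here would lower Hoxc10 and could not raise Isl1 so far. More proximal tissue in the KO pools stays open, with a median of 0.13 over the 12 proximal genes in replicate 1 and 0.58 in replicate 2. The loss of Lmx1b itself, the difference that the design names, also stays open and was not tested apart from these.

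The count of genes called over the 3 stages was set against other splits of the arrays within stages. Of 100 splits drawn from 108, the real one included, 1 gave as many as 37 genes, the real one. The highest of the others gave 2. This argues against chance assignment of the arrays for this count, as far as 100 splits of the same 12 arrays can tell.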

How the results depend on the processing

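The fit without both KO replicate 2 arrays, and the estimated correlation in fits without these or without KO 12.5 dpc replicate 2, were chosen after the data were seen; all other alternatives were planned. For 69 gene results, 1515 alternative values were computed: 1158 kept direction and side of the threshold, 351 kept direction without passing, 2 passed newly and 4 had the opposite sign. These 4 were values of other probe sets, 0.22 for Igdcc3, 0.28 for Meis1 and, for Ttn, -0.022 from 11.5 to 12.5 dpc and 0.15 from 12.5 to 13.5 dpc. Their cause was not tested. The 69 results were the named ones called in the main fit and that of Lmx1b at 13.5 dpc. Other named genes that were not called, such as Pax1 at 11.5 dpc, are not among them. In KO minus WT over the 3 stages, 37 genes became 24 with all probe sets, 24 with the mean of probe sets, and 6 to 434 with 1 array left out. At 11.5 dpc, 3 became 14 with array quality weights, 7 without both KO arrays and 0 to 5 with 1 array left out. At 12.5 dpc, 7 became 63 with all probe sets, 4 with the mean of probe sets, 4 with renewed quantile normalization, 2 with array quality weights, 17 at a threshold of 0.1, 94 without both KO arrays, 1 from the stage alone and 1 to 515 with 1 array left out. At 13.5 dpc, 5 became 14 with an intensity trend, 17 at a threshold of 0.1, 11 without both KO arrays, 11 from the stage alone and 0 to 56 with 1 array left out. The difference of the KO effect between 13.5 and 11.5 dpc had 2 genes with the mean of probe sets, 1 with an intensity trend, 1 with array quality weights, 1 at a threshold of 0.1 and 0 to 12 with 1 array left out; between 12.5 and 11.5 dpc the range was 0 to 38, and between 13.5 and 12.5 dpc 0 to 46. The WT changes gave 5950 and 6940 genes without both KO arrays, and 814 to 4726 and 1663 to 5783 with 1 array left out. Leaving out arrays of groups outside a comparison does not alter its differences. Counts that moved in such fits, among them the WT counts without KO arrays, moved only through the estimate of the spread shared by all groups. The cause of the other moves was not tested. Without KO 12.5 dpc replicate 1, the KO group of that stage was replicate 2 alone, the array with Hspa1a at 9.36. That fit also took the replicate pair that differed most out of the estimate of the spread.

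The number of lists called became 0 in all 6 contrasts with an estimated correlation, whether all arrays were used, both KO arrays were left out or KO 12.5 dpc replicate 2 was. Over the 3 stages it went from 14 to 8 on ranks, 5 without both KO arrays and 7 to 16 with 1 array left out; at 11.5 dpc from 6 to 3 on ranks, 10 without both KO arrays and 4 to 8; at 12.5 dpc from 4 to 2 to 13; at 13.5 dpc from 15 to 8 to 17; and in WT from 6 to 4 to 6 and from 11 to 8 to 13. Spearman's correlations between stages became 0.0547, 0.232 and 0.0358 without dim genes. Whether replicate numbers pair the samples could not be settled. The deviations of same-numbered KO and WT arrays correlated at 0.19, -0.12 and -0.09 at the 3 stages. At 11.5 dpc the array of another group closest to each KO array was the same-numbered WT array (correlations 0.9977 and 0.9976). With a replicate block, which uses 3 of the 6 residual degrees of freedom, 6 genes passed over the 3 stages, 0 at 11.5 dpc, 1 at 12.5 dpc and 0 at 13.5 dpc. Dim probe sets limit all fold changes; leaving out genes at or below the median in every group kept 28 of the 37 genes.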

Other observations

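The test of genes near Lmx1b as flanking DNA, and the standard error in that of base differences, were chosen after the result was seen, the other tests of this part before. In gene order on chromosome 10, Dcn, Lum, Kera and Epyc follow each other, and all 4 encode small leucine-rich proteoglycans. Over the 3 stages Dcn lay at -1.03 ± 0.22 and Epyc at -0.82 ± 0.18, whereas the next measured genes, Btg1 (-0.09 ± 0.06) and Ccer1 (-0.05 ± 0.06), differed little. All 4 proteoglycan genes had a negative difference at each stage, and over the 3 stages Kera and Lum passed the limma test while Dcn and Epyc did not. In KO the level of Kera stayed between 6.02 and 6.37 in 5 of the 6 arrays and was 7.69 in KO 13.5 dpc replicate 2.

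Among the 37 genes called over the 3 stages were other genes beyond the naming rule, chosen after their values were seen: the netrin receptor Unc5d (-0.89 ± 0.13), the cadherins Cdh10 (-0.58 ± 0.08) and Cdh9 (-0.34 ± 0.05), the protocadherin Pcdh7 (-0.53 ± 0.07) and Slitrk5 (-0.47 ± 0.07), a relative of Slitrk1. The axon guidance list as a whole was not called (adjusted p = 0.277), with 1 member higher and 4 lower when adjusted over the list alone.

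Sex-linked genes differed between pools. Xist lay at 6.49 in KO 12.5 dpc replicate 1 and 6.72 in WT 12.5 dpc replicate 1, and between 11.18 and 12.86 in the other 10 arrays. The Y-linked gene Kdm5d lay at 3.16 in KO 12.5 dpc replicate 2 and between 2.88 and 5.55 in the 4 arrays of 13.5 dpc.

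A hypothesis for the lower cartilage, tendon and proteoglycan genes is that KO limbs were less advanced than WT limbs of the same stage. The genotype difference should then run against the WT change between stages, taken from stages that share no array with it. Spearman's correlation across genes was -0.04 at 11.5 dpc, -0.11 at 12.5 dpc and -0.029 at 13.5 dpc. In replicate 1 alone it was 0.05 at 12.5 dpc and 0.16 at 13.5 dpc, and in replicate 2 -0.21 and -0.19. The 3 values are weak and other splits of a stage gave up to 0.16, 0.18 and 0.30 in size, so the test leaves the hypothesis open.

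Called genes within 150 genes of Lmx1b numbered too few for Fisher's exact test to decide on flanking DNA of another strain (p = 0.218, odds ratio interval 0.10 to 25.4). The 1 called gene among them, Cercam, had no other probe set, so base differences under single probe sets were not measured there. For Trub2, which lies just beyond, the 2 other probe sets showed a median of 0.675 of the called change. On average they exceeded 0.5 of it by 0.06 on the log2 scale (SE 0.07), within the error, so base differences stay open for this gene too.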
